A study of Mus musculus with 6 samples.

How the data were processed

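Thymocytes of 4-week-old mice were fixed in formaldehyde, and the input library was prepared from wild-type cells as the negative control of the Ikaros ChIP, per the labels' protocols. Per the labels, reads were mapped with Bowtie to mm9, peaks over background were called with Sole-Search and coverage was computed with BEDtools. The versions and settings of these tools, the treatment of reads with several matches and any removal of duplicates are not given in the sources used here. The deposited signal of the input is coverage: whole-number read depth per interval, with the lowest listed depth at 1 and the highest at 5162992, and no normalization visible in the values. It covers 35 chromosomes and contigs, of which 13 are unplaced contigs. Of the 6 samples, 1 had a coverage table that was used. The peak lists and the coverage of the ChIP libraries were not analysed here, which leaves out the comparison of wild type with the ZnF1 and ZnF4 mutants.

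Samples were grouped by the genotype and antibody in the labels. Coordinates are mm9 (NCBIM37), counted from 1, and gene positions came from the GENCODE annotation of that assembly. Depth sums were divided by 51, the length of isolated intervals, to give read equivalents. Fixed-length intervals of overlapping reads cannot be separated in coverage, so read equivalents are not a count of molecules and PCR copies are included. Isolated intervals of depth 2, where a pair of reads share one position, made up 4.79% (4.76 to 4.82) of those before the depth step on chromosome 2 and 2.47% (2.45 to 2.50) of those after it. Read starts per base of unique sequence were 0.355% and 0.164%, and random placement would give a share of depth 2 below these rates. The isolated intervals were taken from all sequence, so the comparison is not like for like.

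No test across samples was possible with 1 library, and no p-values were computed. Ratios of read counts carry 95% intervals from the exact binomial split of Poisson counts, single counts carry exact Poisson intervals and shares carry exact Clopper-Pearson intervals. The limit allowed by a count of 0 was set at 3 counts. Intervals of list medians are order-statistic intervals over the genes of a list. Promoter intervals of single genes cover the promoter count only.

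The following measures were set before the data were examined. The depth of a chromosome was the 75th percentile of its 1-kb windows, divided by the median autosome. Each receptor locus, from the first to the last annotated segment, was compared with 2 Mb on each side after a gap of 200 kb, and placed among 10000 random autosomal windows of its length. Segments were runs of at least 2 steps of 50 kb whose 75th percentile lay under 0.75 or over 1.33 of the chromosome value, with at least 25 non-zero 1-kb windows per step, and 20 Poisson simulations gave the number expected by chance. Pile-ups were 1-kb windows over 20 times the median autosomal window, merged within 5 kb. Promoter depth was the mean within 500 bases of the transcription start over the mean 3 to 10 kb away on both sides, for 9 lists of 139 genes written beforehand, each set against 10000 random lists matched on flank depth. The genes Adgre1, Ahsp and Sox1 were not found under these names in the annotation or had no flank depth. Broad variation was the variance of 100-kb windows over their counting variance.

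The named items were also fixed beforehand: every chromosome, the 6 receptor loci, up to 10 longest low and 10 longest high segments, the 10 largest pile-ups, and per gene list the 4 highest and 2 lowest promoters with a set of genes named whatever their value, among them Ikzf1, Rag1, Cd4, Cd8a, Cd3e and Alb. Some items that this rule takes are not reported here. The parts of the receptor loci and the windows of the local scan were chosen after the data had been seen.

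Restriction to unique sequence was added after the data had been seen, because repeats dominated the planned measures. A bin of 100 bases was called unique when the 25-base sequences sampled every 20 bases in it and in both neighbours occurred once in the genome. Depth in unique bins was limited to 5 per interval. Copy-number classes used the same 25-base sequences and left out bins above a depth of 50. Matching on GC content compared each bin with autosomal unique bins of the same GC content, in steps of 2%, on the same side of the depth step. The local scan used 100-kb windows with at least 20 kb of unique sequence.

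The depth step was noticed in the data and then located by fitting a change between a pair of Poisson rates to reads in 10-kb windows of unique sequence. A least-squares fit to depth adjusted for copy class, tried first, was replaced because the drop at its position was smaller. Repeat families with copies on both sides of the step were also compared copy against copy, weighted by the copies on each side. Ratios of sequence with 100 or more copies were first computed on depth limited to 5, which that class exceeds, and were recomputed on the full depth after this had been noticed.

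The procedures were tested on simulated reads. On the unique layout of chromosome 14, with windows lowered to 0.5 of their level, the scan recovered a median of 0.482 in 20 windows and put 0% of 1075 unchanged windows under 0.67. With windows lowered to 0.75 it recovered a median of 0.741 and put 5% of them under 0.67. Chromosome 14 lies in the deeper part of the data, so the scan was also run 5 times on reads drawn at a flat rate over each chromosome and side of the step. Of 1000 simulated intervals of a ratio of rates, 95.9% held the true ratio. Simulated steps on chromosome 2 were placed with errors of 1, 4 and 1 windows of 10 kb. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

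Alternatives covered the window statistic and size, the treatment of empty windows, a limit on depth, flank lengths, locus ends, segment and pile-up thresholds, promoter and flank widths, and, added later, unique sequence, GC matching, GC matching of promoters, the choice of reference autosomes and the sides of the depth step.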

Results

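Ikaros, the zinc finger transcription factor encoded by Ikzf1, is required for normal lymphocyte development. The design text set chromatin immunoprecipitation with sequencing (ChIP-seq) for Ikaros in whole thymus of wild-type mice against mice mutant for zinc finger 1 or zinc finger 4 of the protein. The 6 samples, all from animals of 4 weeks, comprised 2 wild-type ChIP libraries, 2 from the ZnF1 mutant, 1 from the ZnF4 mutant and 1 wild-type input. Input is fixed chromatin that is sequenced without the antibody step and serves as the background of a ChIP. Coverage of the input was analysed, and the comparison of Ikaros binding between genotypes was not analysed here. With 1 library there were no replicates, so no difference could be set against a spread between animals. Every interval is a 95% interval that covers counting error only, with 2 exceptions. Those of gene list medians cover the spread between the genes of a list, and that of repeat families comes from resampling the families.

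The input coverage consisted of 85545543 intervals with a summed depth of 4435343168 bases. Of the intervals that touched no other, 99.4% were 51 bases long, and the sum corresponded to 86967513 reads of that length. Reads covered 34.4% of the assembled bases of the chromosomes. Sequence that occurs once in the genome, called unique here, made up 54.2% of the autosomes (1298 Mb) and held 3488807 of these read equivalents.

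Developing T cells build their antigen receptor genes by joining variable (V), diversity (D) and joining (J) segments and removing the DNA between many of them, and B cells do so at the immunoglobulin loci. In unique sequence, all 3 T cell receptor loci had lower input depth than the flanking chromosome. The ratio to the flanks was 0.515 (interval 0.478 to 0.555) at Tcra-Tcrd on chromosome 14 (53047603 to 54842772, mm9), which holds the alpha and delta chain segments. It was 0.575 (0.503 to 0.656) at Tcrb, the beta chain locus, on chromosome 6 (40841295 to 41508370), and 0.561 (0.429 to 0.721) at Tcrg, the gamma chain locus, on chromosome 13 (19269911 to 19444212). The ratios of the immunoglobulin loci were 0.846 (0.798 to 0.896) for the heavy chain locus Igh on chromosome 12, 0.767 (0.697 to 0.843) for Igk on chromosome 6 and 0.657 (0.540 to 0.794) for Igl on chromosome 16.

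Among random autosomal windows of the same length, 0.0202% had a lower unique ratio than Tcra-Tcrd, 0.132% a lower one than Tcrb and 0.145% a lower one than Tcrg. The corresponding shares were 7.85% for Igh, 1.91% for Igk and 0.726% for Igl. After matching on GC content, the T cell receptor loci had ratios of 0.544 at Tcra-Tcrd, 0.636 at Tcrb and 0.614 at Tcrg, while Igh stood at 1.01, Igk at 0.958 and Igl at 0.857. The depth behind these ratios was 791 read equivalents in 354.7 kb at Tcra-Tcrd, 242 in 266.1 kb at Tcrb and 61.4 in 33.9 kb at Tcrg. Restricting the measure to unique sequence was decided after the data had been seen. The measure fixed beforehand, the 75th percentile of 1-kb windows over all sequence, gave 0.959 at Tcra-Tcrd, 1.05 at Tcrb, 2.04 at Tcrg, 2.62 at Igh, 2.34 at Igk and 4.18 at Igl. By that measure the T cell receptor loci did not stand below other regions, with Tcra-Tcrd at percentile 44.0, Tcrb at 58.6 and Tcrg at 95.1 of the random windows.

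Within Tcra-Tcrd, depth was lower from both ends towards the D-delta segments, as far as unique sequence allowed a measure. The stretch from Trav1 to Trav18 held only 103.4 kb of unique sequence, with almost none between 53300001 and 54380000. The unique ratio was 1.42 (1.21 to 1.65) in the 100 kb before Trav1, 0.709 (0.631 to 0.793) from Trav1 to Trav18 and 0.555 (0.433 to 0.699) from Trav18 to Trdv1. It was 0.330 (0.280 to 0.387) from Trdv1 to Trdv4 and lowest, 0.209 (0.135 to 0.308), between Trdv4 and Trdd1 (54695190 to 54733143). From Trdd1 to Traj59 it was 0.297 (0.207 to 0.414). It stood at 0.684 (0.536 to 0.860) in the 5′ part of the Traj segments, at 0.738 (0.592 to 0.908) in their 3′ part, and at 0.887 (0.767 to 1.02) in the 100 kb beyond Trac, the constant gene of the alpha chain. After matching on GC content, the parts from Trav1 to Traj59 stood, in the same order, at 0.823, 0.619, 0.351, 0.205 and 0.284. The 5′ and 3′ parts of the Traj segments then stood at 0.650 and 0.695.

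At Tcrb depth was already lower outside the locus, with a ratio of 0.625 (0.479 to 0.801), or 0.711 after matching on GC content, in the 100 kb before Trbv1. The ratio was 0.995 (0.797 to 1.23) from Trbv1 to Trbv2, 0.529 (0.395 to 0.693) from Trbv2 to Trbv16 and 0.414 (0.301 to 0.555) from Trbv16 to Trbv30. Between Trbv30 and Trbd1 (41231989 to 41483200), where trypsinogen genes such as Prss1, Prss2, Try4 and Try5 lie, it was 0.239 (0.148 to 0.366) from 21.3 read equivalents. The D-beta and J-beta segments, from Trbd1 to Trbj2-7, had a ratio of 0.144 (0.0174 to 0.520) from 2.12 read equivalents. Between Trbj2-7 and Trbv31, the V segment that lies beyond the constant genes, the ratio was 1.52 (1.04 to 2.15). After matching on GC content, the parts from Trbv1 to Trbv31 stood, in the same order, at 1.145, 0.559, 0.477, 0.275, 0.138 and 1.43. At Igh no drop was detectable in the J and D segments, where the ratio was 0.997 (0.732 to 1.327), and its 3′ V segments stood at 0.782 (0.713 to 0.857), or 0.981 after matching on GC content. The middle part of the Igh V segments stood at 0.762 (0.686 to 0.844), or 0.992 matched, and the 5′ part at 1.12 (0.883 to 1.41), or 1.504 matched. At Igk the V segments, from the part farthest from the J segments to the nearest, stood at 0.648 (0.553 to 0.755), 0.826 (0.680 to 0.995) and 0.877 (0.758 to 1.01), or 0.813, 1.09 and 1.07 after matching on GC content. The stretch from Igkj1 to Igkc held only 3 read equivalents.

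**Figure D1:**
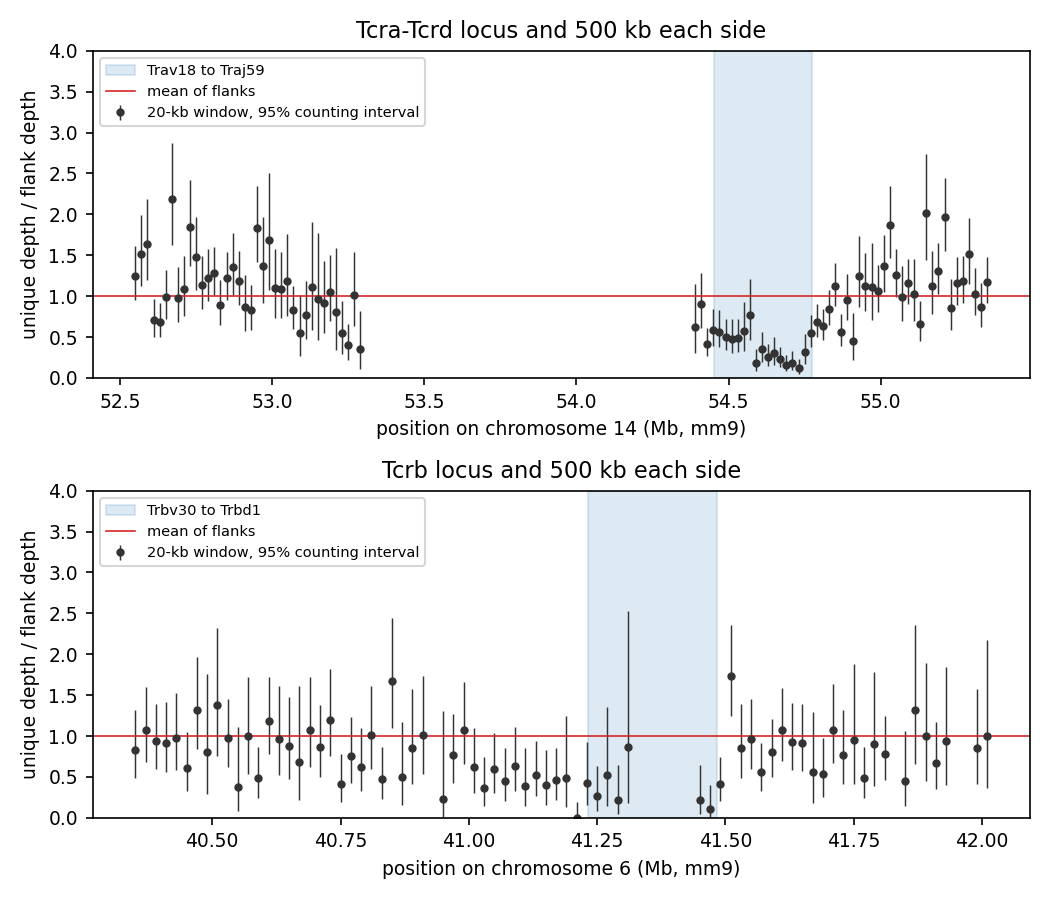
Unique input depth in 20-kb windows, divided by the mean of the flanks, against position in Mb over Tcra-Tcrd and Tcrb with 500 kb on each side; points are windows of the 1 library, bars their 95% counting intervals, and windows with under 2 kb of unique sequence are left out. The shaded stretches, Trav18 to Traj59 and Trbv30 to Trbd1, had ratios of 0.343 and 0.239.

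A scan of unique sequence in 100-kb windows against the windows within 2 Mb, added after the data had been seen, gave its lowest values at the T cell receptor loci. Of 23826 windows, 1477 fell under 0.75 of their surroundings, where reads drawn at a flat rate gave a mean of 129.6 in 5 simulations. In the order of the coverage data, 628 of the low windows lay before a drop in depth on chromosome 2, against 6.2 simulated, and 849 after it, against 123.4. Another 1608 windows lay above the upper bound set for high segments, against 42.6 simulated. The 4 lowest lay in Tcra-Tcrd and Tcrb: 0.247 at chromosome 14, 54600001 to 54700000; 0.290 at chromosome 6, 41200001 to 41300000; 0.300 at chromosome 6, 41400001 to 41500000; and 0.380 at chromosome 14, 54700001 to 54800000. The next was a window without a protein-coding gene on chromosome 4 (71200001 to 71300000) at 0.410 (0.265 to 0.593), whose interval overlaps those of the receptor windows. A window at the Igl constant gene Iglc3 ranked 10 at 0.482 (0.352 to 0.650).

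The scan fixed beforehand, over all sequence and against each chromosome's own level, gave 3608 low and 2695 high segments where Poisson simulation of a flat genome gave 0 in all 20 runs. In unique sequence against local surroundings there were 203 low and 279 high segments, the opposite balance. The longest low segments lay mostly on chromosome 2 past that drop in depth. They held Bcas1, Cyp24a1 and Dok5 (170100001 to 171800000, median ratio 0.518), Lsm14b, Psma7 and Zbtb46 (179750001 to 181150000, 0.436), Macrod2 (140600001 to 141900000, 0.435), Spred1 and Rasgrp1 (116450001 to 117650000, 0.433), Slc9a8, Snai1 and Nfatc2 (167300001 to 168500000, 0.561), and Cdh4 and Taf4a (178550001 to 179700000, 0.360). The others were the Six2 and Prkce region of chromosome 17 (86050001 to 87450000, 0.557) and 3 regions of X: Tnmd to Zmat1, with 5 Armcx genes (0.512), Rnf128 to Mid2 (0.473), and Gm14483 to Bcor (0.388). In unique sequence against local flanks the same 10 regions had ratios from 0.860 at Bcas1 to 1.19 at Tnmd to Zmat1.

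The longest high segments held multi-copy gene families in some cases, but not in all. They included the Sult2a sulfotransferase and Obox homeobox clusters of chromosome 7 (14000001 to 16500000, median ratio 2.76), a cluster of 11 Gm genes also on chromosome 7 (32300001 to 33600000, 2.78), 28 Olfr olfactory receptor genes on chromosome 2 (36100001 to 37200000, 5.73), the Il1f8 and Il1f9 region of chromosome 2 (23050001 to 24100000, 3.66), the Vmn2r58 region of chromosome 7 (48900001 to 50000000, 2.36), Alkbh8 to Kbtbd3 on chromosome 9 (3300001 to 4400000, 2.83) and Gm10801 with Gm10800 on chromosome 2 (97500001 to 98650000, 3.45). The Slx region of X (25100001 to 26250000) stood at 2.08. A stretch of chromosome 2 (94650001 to 96100000, 2.22) and one of chromosome 10 (47500001 to 48800000, 1.76) held no protein-coding gene. Unique sequence at the Sult2a and Obox clusters was at 0.990 (0.874 to 1.12) of its flanks, and at the Olfr cluster at 0.932 (0.871 to 0.997). The Gm10801 and Gm10800 segment spans the drop in depth, so its parts were set against flanks on the same side: the part before the drop stood at 1.03 (0.960 to 1.10), and 54.6 kb after it at 1.37 (1.10 to 1.69).

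Chromosomes fell into 2 levels that followed their order in the coverage data rather than their identity. Chromosomes 1 and 10 to 19 had unique depths from 0.171 on chromosome 16 to 0.2001 on chromosome 11. Chromosomes 3 to 9 had depths from 0.0770 on chromosome 3 to 0.0876 on chromosome 7. Chromosome 2, which lies between these sets in that order, carried both levels, 0.174 before and 0.0850 after a step at 98.51 Mb. Within 1 Mb of the step the ratio of the levels was 2.19 (1.98 to 2.44), and within 5 Mb it was 2.12 (2.04 to 2.20). Sequence with over 1000 copies, located on its own, placed the step at the same 98.51 Mb. By the measure fixed beforehand, the ratio to the median autosome ran from 0.986 on chromosome 19 to 1.12 on chromosome 1 in the first set, from 0.450 on chromosome 9 to 0.523 on chromosome 3 in the second, and was 0.727 on chromosome 2.

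**Figure D2:**
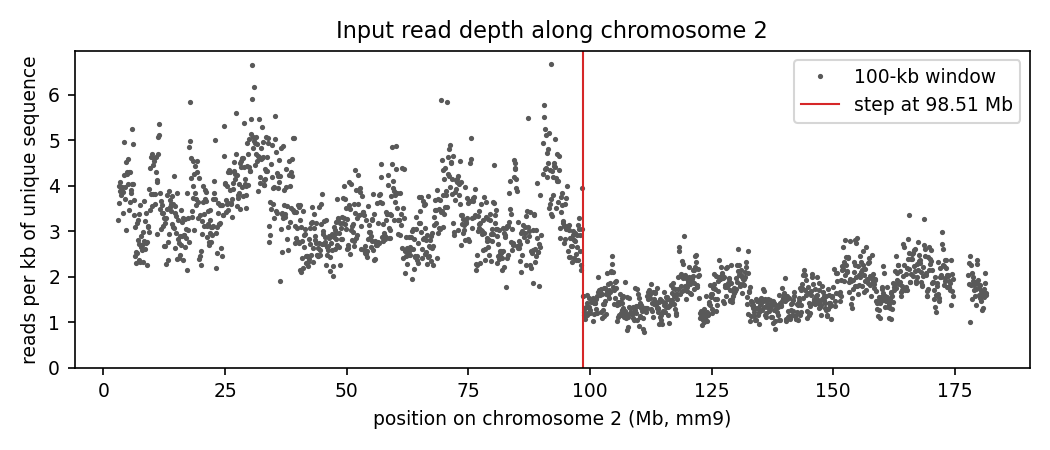
Read equivalents per kb of unique sequence (vertical axis) in 100-kb windows along chromosome 2 (horizontal axis, Mb, mm9) in the 1 input library; each point is a window and the line marks the step at 98.51 Mb. Mean unique depth was 0.174 before the step and 0.0850 after it.

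The X chromosome belonged to the later part of the order, and its level depended on the reference. Against the median of all autosomes it stood at 0.815 (0.815 to 0.816) by the measure fixed beforehand, and at 1.69 against the autosomes after the step. In unique sequence against the autosomes of the same part it stood at 0.895 (0.889 to 0.901), and at 1.04 after matching on GC content. The Y chromosome stood at 0.193 (0.190 to 0.195) of the median autosome over all sequence, and at 0.400 (0.395 to 0.405) of the median of the autosomes that follow the step as it does. Its unique sequence, 315.1 kb, held 1.16 read equivalents (0.0253 to 5.57), where a chromosome present in 1 copy per cell would have given 258 and 2 copies 515. Sequence of Y with over 1000 copies in the genome had 1.00 times the depth of the same class on the autosomes. The mitochondrial chromosome had a ratio of 4.81 (4.59 to 5.04) to the median autosome and of 9.99 (9.54 to 10.5) to that of the autosomes after the step. Over all sequence, the intervals of X, Y and the mitochondrial chromosome scale the ratio by the counting error of all reads of the chromosome. They leave out the spread of its windows and the error of the reference, and so are too narrow for the percentile.

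Most reads lay outside unique sequence. Depth rose with the number of copies a sequence has in the genome, from 0.181 in unique sequence before the step to 0.617 at 3 to 10 copies, 2.46 at over 100 and up to 1000 copies and 7.62 above 1000 copies. After the step these values were 0.0835, 0.376, 1.11 and 3.48. Sequence with exactly 2 copies was the exception, at 0.144 before and 0.0647 after the step, which is 0.792 and 0.775 of unique depth. Unlike these 2 classes, those of 3 or more copies did not require neighbouring bins of the same class. Reads of adjoining repeats can add to their depth, so the rise from 2 copies to 3 to 10 copies is not like for like.

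**Figure D3:**
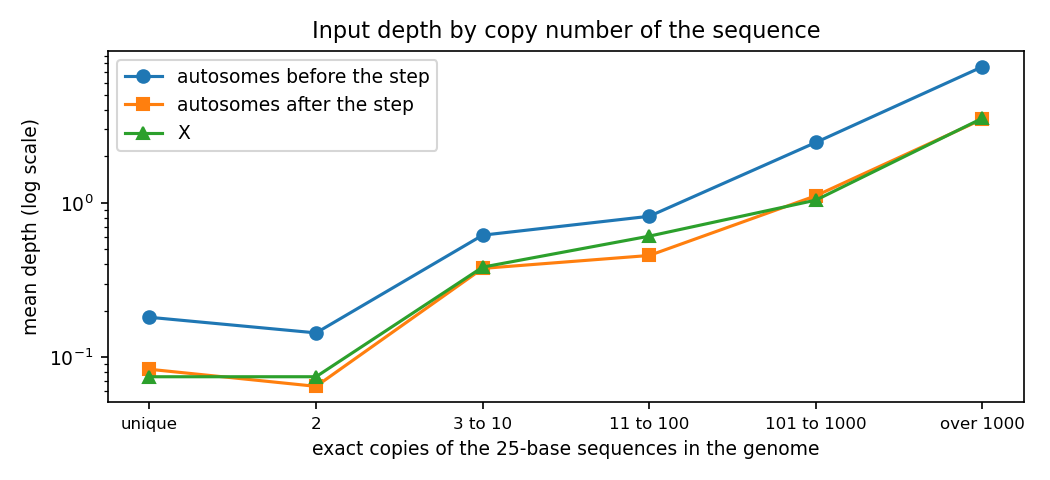
Mean input depth (vertical axis, log scale) by the number of exact copies of a sequence in the genome (horizontal axis) for autosomes before the step, autosomes after the step and X in the 1 library. Depth ran from 0.144 at 2 copies to 7.62 above 1000 copies before the step, and from 0.0647 to 3.48 after it. Only unique and 2-copy bins also needed neighbours of their own class, and bins that met no class were left out.

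Of the 1-kb windows, 36213 had more than 20 times the median autosomal depth. Merged within 5 kb they formed 14454 pile-ups and held 45.5% of all depth. The largest, 6 kb on chromosome 2 (98502001 to 98508000) over the predicted genes Gm10801 and Gm10800, held 19.6% of all depth and ended 2 kb before the fitted step. The step was placed only to 10-kb windows, so the pile-up may lie at the step itself. The next, 39 kb at the centromeric end of chromosome 9 (3000001 to 3039000) over predicted genes such as Gm10722 and Gm10715, held 13.8%. Smaller ones lay on chromosome 12 (3103001 to 3111000, 1.07%), on chromosome 9 near Gm5614 (35112001 to 35114000, 0.755%), in Chl1, a neural cell adhesion gene, on chromosome 6 (103599001 to 103600000, 0.504%), in 2210408I21Rik on chromosome 13 (77571001 to 77579000, 0.499%) and on X at 35134 bases from Pak3 (139917001 to 139918000, 0.151%). Another 3, with 0.445%, 0.216% and 0.190%, lay in unplaced contigs. Together these 10 held 37.3% of all depth.

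Open promoters can yield more or fewer input fragments than other sequence, so depth within 500 bases of transcription starts was compared with depth 3 to 10 kb away. Promoters were lower than their flanks, with a median ratio of 0.188 over 22226 genes and 9.59% of genes above 1. In unique sequence, against flanks 10 to 50 kb away, summed promoter depth was 0.761 (0.753 to 0.769) of that of the flanks. The unique ratio was 0.423 (0.400 to 0.447) above 70% GC, against 0.919 (0.898 to 0.941) between 40% and 50% GC, and 0.690 (0.653 to 0.729) under 40% GC. Unique depth also fell at high GC content away from promoters, before the step from 0.219 at 48% GC to 0.152 at 68%. Matched on the GC content of sequence over 5 kb from any transcription start, the ratios were 0.707 (0.658 to 0.757), 0.845 (0.825 to 0.865) and 0.721 (0.682 to 0.761), and 0.801 (0.792 to 0.809) over all promoters. Above 70% GC a reference existed for only 39.8% of the promoter bins.

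The thymocyte list, 30 genes of T cell receptor signalling, rearrangement and T lineage control, had a median of 0.253 (0.164 to 0.394), at percentile 76.5 of random lists matched on flank depth. In unique sequence its ratio was 0.973 (0.768 to 1.23), at percentile 93.4 of 1000 random lists, against 0.761 over all genes. Some lists of other tissues lay near it, with thymic epithelial genes at percentile 89.3, neuronal genes at 86.7, myeloid genes at 82.8 and B cell genes at 77.4. Lower were liver genes at 71.6, developmental genes at 66.2, housekeeping genes at 62.5 and erythroid genes at 60.1. Ptcra, the pre-T cell receptor alpha chain, was highest at 1.497 (1.04 to 2.11), followed by Cd2 at 1.40, Ets1 at 1.39 and Cd8b1 at 1.17. Cd3e and Tox were among 4 genes of the list with no read at the promoter. Ikzf1 itself (transcription start at 11585006 of chromosome 11) had 1 read equivalent and a ratio of 0.0630 (0.00160 to 0.351), Rag1 0.164, Cd4 0.0736 and Cd8a 0.370. Housekeeping genes had a median of 0.133 (0.0872 to 0.263), with Rplp0 at 2.02, Hprt at 0.710, Ywhaz at 0.432 and Eif4a1 at 0.399, and no read at Rps3 or Hnrnpa2b1.

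Among lists of other blood cells, the 7 erythroid genes had the highest median, 0.826 (0 to 1.74), at percentile 99.0 of matched random lists. Slc4a1, the erythrocyte anion exchanger, stood at 1.74 (1.14 to 2.53), Klf1 at 1.27, Epb4.2 at 1.03, Gata1 at 0.826 and Alas2 at 0.277. In unique sequence the erythroid list had a ratio of 0.799 (0.373 to 1.43) from 10.3 read equivalents, so no excess was detectable at this depth. The B cell list had a median of 0.394 (0.120 to 1.05), with Ebf1 at 1.48, Cd79a at 1.05, Cd22 at 1.00, Pax5 at 0.822, Blk at 0.120 and Ms4a1 at 0.0603. The myeloid list had a median of 0.2496 (0.0385 to 1.31), with Elane at 1.64, Cd68 at 1.31, Csf1r at 1.29, Lyz2 at 0.328, Ctsg at 0.0385 and no read at Itgam.

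Thymic epithelial genes had a median of 0.177 (0 to 0.709), with Aire at 0.709, Psmb11 at 0.307, Epcam at 0.287, Krt5 at 0.258, Krt8 at 0.0464 and no read at Cldn4. Liver genes had a median of 0.313 (0.0509 to 0.691), with Tat at 1.34, Apoa2 at 0.869, Alb at 0.691, Hpd at 0.654 and no read at Ttr or Fga. Neuronal genes had a median of 0.280 (0.0999 to 0.699), with Gria1 at 3.70 (2.54 to 5.19), Rbfox3 at 1.17, Slc17a7 at 0.699, Slc32a1 at 0.692, Snap25 at 0.0919 and no read at Stmn2. Developmental genes with CpG islands had a median of 0.252 (0.150 to 0.598), with Tbx5 at 5.70 (3.57 to 8.63), Gata4 at 2.61, Foxa2 at 1.85, Hoxc8 at 1.65, Hoxb1 at 0.0695 and no read at Hoxa13. In unique sequence the interval of every list included 1, from 0.799 for erythroid genes to 1.10 (0.720 to 1.59) for thymic epithelial genes. With promoters taken as 1 kb on each side, the medians of B cell (0.981), myeloid (0.701), liver (0.558), developmental (0.427), thymocyte (0.412) and housekeeping genes (0.217) were over 1.5 times higher, and with flanks of 10 to 50 kb those of liver (0.113), developmental (0.136) and myeloid genes (0.148) over 1.5 times lower. A named gene rested on at most 39.5 read equivalents, most of them outside unique sequence where the interval lay above 1. Unique sequence held 3 of 33 at Gria1, where its flanks would give 1.30, 2 of 22 at Tbx5 against 0.396, 8.39 of 39.5 at Gata4 against 1.83, 8.73 of 33.8 at Ptcra against 2.81 and 4.12 of 27.02 at Slc4a1 against 2.98. Of the 20 named promoters above 1, 5 had fewer read equivalents in unique sequence than their flanks would give: Elane 1 against 2.30, Klf1 1 against 1.81, and none at Tat, Hoxc8 and Rplp0 against 1.78, 2.25 and 0.781. Some named promoters below 1 held more in unique sequence than their flanks would give, such as Alb with 4 against 0.883 and Aire with 7.20 against 3.17. Others held fewer, such as Ikzf1 with 1 against 3.64 and Cd4 with 0.765 against 2.06.

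Along the autosomes, the variance of depth between 100-kb windows was 5315715 times the counting variance over all sequence, where few deep intervals set the value, and 34.5 times in unique sequence. These values pool both sides of the depth step, and in unique sequence the ratio was 20.9 before the step and 5.81 after it. The Spearman correlation between neighbouring windows in unique sequence, across windows of this library, which are not independent replicates, was 0.903 over both sides, 0.678 before and 0.646 after the step. Depth and GC content were related in opposite directions. Their Spearman correlation over all sequence was -0.414 over both sides, -0.511 before and -0.538 after the step, and in unique sequence it was 0.340, 0.751 and 0.720.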

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

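The tests of 2-copy depth were chosen after the depth of the copy classes had been seen, and the tests on pairs and families of copies were written before their results. Read equivalents in 3 parts of the assembly outside the autosomes, X and Y lay above the 3 that a count of 0 allows, and no control library was analysed. Any part that holds more than a few reads passes this limit, so it does not mark these parts as unusual. Unplaced contigs without a chromosome held 968319, unplaced contigs of Y held 155430 and the mitochondrial chromosome held 1812. Unplaced contigs are rich in satellite repeats, and the reads on contigs of Y contrast with 1.16 read equivalents in the unique sequence of Y.

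Depth was higher in high-copy sequence. Placing each read at several positions as the cause is argued against by 2-copy sequence, which before the step had 0.792 of unique depth instead of more, and by pairs of identical copies, whose summed depth was exactly equal in 1.53% of the pairs that held reads. In families of over 100 and up to 1000 copies the variance between copies over their mean was 1.18 before and 0.948 after the step, near the value of 1 that random placement gives. Placing each read once at random stays open, with 2-copy sequence at 0.775 of unique depth after the step and reads in both copies of 20.8% of pairs. These values cannot decide it, since the limits set for them were wide. Random placement alone would give 2-copy sequence the depth of unique sequence, and both measured values lay below that. The share of pairs with reads in both copies that random placement would give was not computed. Families of over 100 and up to 1000 copies had 14.6 times unique depth before and 13.9 times after the step. If each read was placed once, a candidate explanation is that the library held more reads of repeats than their share of the assembly. Whether this came from copies missing in the assembly or from the preparation of the chromatin was not tested, and the design names no group that would give a biological explanation.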

How the results depend on the processing

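Unique sequence, GC matching, the later reference autosomes and the sides of the depth step were chosen after the data had been seen; the other alternatives were set before. Of the alternatives set beforehand 42 values stayed within their interval or within 1.5 times the main count, 53 moved and 6 changed side of 1, and of the added ones 4, 25 and 13 did. For X and Y that interval is only the counting error of all reads of the chromosome, so small changes count as moved. Leaving out a replicate could not be done with 1 library. No paired analysis was possible because 1 library was analysed. Where not stated, the cause was not tested. The mean unique depths of 0.181 and 0.0835 limit what can be said of stretches of a few kb.

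With the median of 1-kb windows, X stood at 0.782, Y at 0, Tcra-Tcrd at 0.633, Tcrg at 1.21, Igh at 2.81, Igk at 2.0 and Igl at 1.54, and Tcrb changed side to 0.80. With the mean, X stood at 0.725, Y at 0.386, Tcrg at 1.56, Igh at 2.40, Igk at 1.91 and Igl at 2.54, and Tcra-Tcrd changed side to 1.01. In 5-kb windows, X stood at 0.898, Y at 0.358, Tcrb at 1.19, Tcrg at 1.98, Igh at 2.87, Igk at 2.45 and Igl at 3.50, and Tcra-Tcrd changed side to 1.15. With non-empty windows alone, X stood at 0.904, Y at 0.846, Tcrb at 1.26, Igh at 2.66 and Igk at 2.41, and Tcra-Tcrd changed side to 1.00. With depth limited to 5, X stood at 0.882, Y at 0.213, Tcrg at 1.74, Igh at 2.32, Igk at 2.25, Igl at 2.89 and the variance ratio at 413, which shows that few deep intervals set the main value of that ratio.

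With flanks of 1 Mb, Tcrg stood at 2.42, Igh at 2.90, Igk at 2.28 and Igl at 3.92, and Tcra-Tcrd changed side to 1.01. With flanks of 5 Mb, Tcrb stood at 1.00, Tcrg at 1.87, Igh at 2.25, Igk at 1.96 and Igl at 4.03, and Tcra-Tcrd changed side to 1.07. With loci shortened by 10% at each end, Tcrg stood at 2.58, Igh at 2.55 and Igk at 2.06. In unique sequence, Tcra-Tcrd stood at 0.515 and the variance ratio at 34.5, while Tcrb (0.575), Tcrg (0.561), Igh (0.846), Igk (0.767) and Igl (0.657) changed side. With GC matching as well, Tcra-Tcrd stood at 0.544 and Igh at 1.01, while Tcrb (0.636), Tcrg (0.614), Igk (0.958) and Igl (0.857) changed side.

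Against the autosomes after the step, X changed side to 1.69 and Y stood at 0.400, since the median of all autosomes comes from the deeper part. In unique sequence X stood at 0.433 and Y at 0.00109 of all autosomes, and at 0.895 and 0.00225 of those after the step. With GC matching X changed side to 1.04 and Y stood at 0.00286. Over all sequence the variance ratio was 28374 before and 5380981 after the step, and in unique sequence 20.9 and 5.81.

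In 100-kb steps there were 1581 low and 1267 high segments, and in the unique local scan 203 and 279. Pile-ups over 10 times the median numbered 50105 with 59.4% of depth, and over 50 times the median 303 with 38.2%. Without the mitochondrial chromosome and unplaced contigs they held 45.1%.

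Within 1 kb of the transcription start the median was 0.412 for thymocyte, 0.217 for housekeeping, 0.981 for B cell, 0.701 for myeloid, 0.558 for liver and 0.427 for developmental genes, of which the thymocyte value lay outside its main interval. With flanks of 10 to 50 kb it was 0.113 for liver, 0.148 for myeloid and 0.136 for developmental genes, of which the developmental value did. In unique sequence, summed over each list, the ratio was 0.973 for thymocyte, 0.80 for housekeeping, 0.857 for liver, 0.955 for neuronal and 0.820 for developmental genes, and it changed side for myeloid (1.00) and thymic epithelial genes (1.10). Matching promoters on GC content gave 0.845 at 40% to 50% GC, 0.812 at 50% to 60%, 0.770 at 60% to 70%, 0.707 above 70% and 0.801 over all.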

Other observations

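The tests of the depth step, of GC content, of an inherited deletion and along the J-alpha segments were chosen after the results had been seen, and the test of high-copy sequence inside the receptor loci was written before. The highest windows of the local scan of unique sequence were chosen after their values were seen. The window of Sfi1 and Drg1 on chromosome 11 (3000001 to 3100000) had 21.4 times (20.5 to 22.3) the depth of its surroundings, and that of the Ugt1a glucuronosyltransferase genes on chromosome 1 (90100001 to 90200000) had 5.26 times (5.01 to 5.52). A pair of neighbouring windows on chromosome 14 stood at 2.23 (2.05 to 2.41) with Slc25a37 and Entpd4, and at 2.06 (1.89 to 2.24) with Loxl2. Other high windows held Sms and Mbtps2 (2.16), Ide and Kif11 (2.03), Mto1 and the translation factor Eef1a1 (2.002), and the chaperonin pair Hspd1 and Hspe1 (1.95).

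Unique depth in the low stretches of the T cell receptor loci was 0.343 (0.304 to 0.386) of the flanks between Trav18 and Traj59 and 0.239 (0.148 to 0.366) between Trbv30 and Trbd1. GC content as the cause is argued against by matched ratios of 0.357 and 0.275. A deletion of a whole stretch from both chromosomes of every cell is argued against by 288 and 21.3 read equivalents in their unique sequence. On 1 chromosome it would give 0.5, and the intervals of 0.343 and 0.239 and of 0.209 (0.135 to 0.308) from Trdv4 to Trdd1 lie below that. They cover counting error only, and the central 95% of random windows of the length of Tcrg ran from 0.706 to 1.40. The stretches were also chosen after the data had been seen, so a deletion on 1 chromosome stays open. From Trbd1 to Trbj2-7, 0.144 (0.0174 to 0.520) came from 2.12 read equivalents and leaves both open. A deletion in some animals of a pool was not tested. High-copy sequence inside the stretches kept ratios of 1.03 (0.994 to 1.07) and 1.02 (0.935 to 1.11), so reads that can come from elsewhere were placed there at the usual rate. Beside the Tcrb stretch, from Trbv16 to Trbv30, high-copy sequence was lower, at 0.730 (0.631 to 0.842) on 4.6 kb. In the other parts of the receptor loci with a value it ran from 0.945 to 1.23. As a hypothesis, the loss of unique depth may reflect V(D)J rearrangement in thymocytes, which would remove DNA between V and J segments in many cells. The test along the J-alpha segments did not decide it, since the 3′ over the 5′ part was 1.08 (0.784 to 1.49). No library of cells without rearrangement was analysed.

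Depth fell at 98.51 Mb of chromosome 2 and stayed low on all chromosomes that follow in the order of the coverage data. GC and repeat content as the cause is argued against by a ratio of 2.19 before to after in bins matched for both, and real copy number by 2.19 in sequence of over 1000 copies, whose reads come from all chromosomes. That part of the reads contributed only up to this point of the order stays open: the ratios in unique sequence and in that of over 1000 copies were within 1.01 times of each other, but those at 3 to 10 copies, 1.64 (1.62 to 1.67), and at 11 to 100 copies, 1.79 (1.77 to 1.82), lay up to 1.32 times below the unique ratio of 2.17. Between copies of the same family the ratio was 2.44 (2.26 to 2.82, resampling families) in 15 families of over 100 and up to 1000 copies, above the unique ratio. It was 2.44 in 5 families of 11 to 100 copies, too few for an interval. That value rests on the weighting: these families held 107 reads on 137 copies before and 196 on 75 copies after, so their plain depth per copy went the other way. Families of 3 to 10 copies held 1 read. The fitted point lies 2 kb past the largest pile-up, a distance finer than the 10-kb windows of the fit. This coincidence was noticed afterwards and not tested, and the design gives no biological explanation to test.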
